A study of Mus musculus with 6 samples.

How the data were processed

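RNA-seq was done on regulatory T cells (Tregs) from the colon of mice with colitis induced by TNBS, a hapten that provokes an inflammation of the bowel wall driven by T cells. Per the labels' protocols, the skin was sensitised with 150 µl of 1% TNBS and 100 µl of 2.5% TNBS was given into the rectum 7 days later. RNA was extracted with Trizol, and 1.3 µg of total RNA entered a stranded poly(A) library kit, per the labels' protocols. The 6 libraries fall into 2 groups by the genotype in their labels, 3 labelled as a knockout (KO) of REV-ERB and 3 labelled wild type (WT). How the Tregs were sorted, and which exons the knockout removes, is not given in the sources used here.

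The authors deposited values in TPM (transcript abundance scaled for transcript length and library size) in a table with 1 row per RefSeq transcript, per the file headers. Each row also gives the transcript's coordinates, its length and the number of its genomic copies. The table has 24537 rows and as many distinct symbols, so no rows had to be merged. FastQC 0.11.8, Trim Galore 0.4.4, STAR 2.5.3a and HOMER 4.9.1 and the build mm10 are named in the submitters' processing notes, which give no order or settings. Whether reads were counted by strand is not given in the sources used here, so overlapping genes on either strand are treated as uncertain. The deposited TPM values sum to between 634200 and 644662 per library, below the total that TPM is scaled to, and the source of the remainder is not given in the sources used here. The start coordinates equal those of the GRCm38 RefSeq gene table for 14482 genes, so they count from 1.

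TPM multiplied by transcript length came out as a whole multiple of a fixed step in each library. Of the values up to 500 reads, 99.99% lay within 0.1 of a whole number in every library, so the reads behind each value were recovered. They add up to 12641848, 13848377 and 15890627 reads in the libraries labelled KO 1, 2 and 3. The libraries labelled WT 1, 2 and 3 hold 9794479, 12122575 and 11678688 reads. Every library labelled KO was therefore deeper than every library labelled WT. A gene with 0 reads in a group was given an upper limit of 3 reads over the group, which covers counting error only. No column of values per sample was left without a sample.

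Genes with a TPM of at least 1 in at least 3 of the 6 libraries were tested, which left 13211. The test was limma's moderated two-sided test with a variance trend on log2(TPM + 1), with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, labelled KO minus labelled WT, which understates the change of genes with low values. R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with matplotlib 3.10.9 were used. An exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1, and it was run for each named gene. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. The replicate numbers did not pair the libraries and were not used as a block.

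Gene lists were fixed before the data were examined, 20 for pathways and T cell programs and 16 for markers of other cells, sex and RNA quality. Each was tested with camera at a preset correlation of 0.01, which compares the genes of a list with the other genes tested, and the p-values were adjusted over the pathway lists and over the marker lists separately. Beside it, camera was run with an estimated correlation, and fry was run as a test of the list alone. With an estimated correlation, camera also takes the few residual degrees of freedom of the 6 libraries. Its p-values therefore rose even where that correlation was low. Cholesterol synthesis, at -0.028, went from a camera p of 0.001729 to 0.02647. A list or family that misses the threshold there need not owe this to correlation between its genes. For each list the members past the threshold were also counted with p adjusted over the list alone. The genes named in the text follow a rule that was also fixed before the data were examined. It takes 10 genes of interest whatever their values, the 10 genes with the smallest p in each direction where fewer than 5 pass the threshold, and per list up to 2 members with the smallest p where none passes over all genes. Any other gene named was chosen after its values were seen; these are the remaining members past the threshold over their list alone, the genes of the closing tests and the gene families of the closing section.

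Of the fixed markers, 11 of the 13 symbols in the list of RNA quality, which includes the mitochondrial transcripts, and the T cell receptor and immunoglobulin constant regions were not analysed here. The list of red blood cell markers kept 2 tested genes, and the lists of neutrophil and of mast cell and eosinophil markers kept 4 each, because the other members were below the minimum TPM.

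The procedure was tested on 5 simulated data sets with the means and depths of these libraries, in each of which 200 genes were changed, with 13190 genes tested on average. It called 1.55% of the genes changed 1.5-fold, 27.3% of those changed 2-fold and 79.7% of those changed 4-fold. Of its calls, 10.9% were false, above the 5% that the threshold aims at. Random lists had a camera p under 0.05 in 2.22% of cases, and a list raised 1.3-fold was found in 5 of 5 simulations. Genes were drawn independently there, so false calls of camera on lists whose genes move together were not tested. Genes of similar level also shared a spread there, and no structure between libraries was simulated. The rates of called and of false genes may therefore differ in these data. The estimated correlation was 0.532 in the oxidative phosphorylation list and 0.517 in the epithelial list. Alternatives covered the pseudocount, the filter, the scaling, the composition, the variance model, the replicate block, the threshold and each library left out. For the composition, 14 immunoglobulin, haemoglobin or mitochondrial genes were left out and the rest was rescaled to the full TPM total. This raised the genes tested to 13758, so its results reflect the rescaling as well. After the data had been seen, 5 more were added, namely voom on the recovered reads, voom on reads thinned to the smallest library, an epithelial score as a covariate, removal of the trends on transcript length and GC content, and leaving out transcripts under 300 bases. Some members of the lists are not reported here.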

Results

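The data are transcript levels of colon Tregs in TNBS colitis from 6 mouse libraries, 3 labelled KO for REV-ERB and 3 labelled WT. REV-ERBα, the product of Nr1d1, is a nuclear receptor that represses transcription and belongs to the circadian clock, and Tregs are the CD4 T cells that restrain immune responses. The comparison of the groups asks how the transcriptome of Tregs in the inflamed colon differs with the loss of REV-ERB. The depth was 12641848 to 15890627 reads per library labelled KO and 9794479 to 12122575 per library labelled WT. Values are TPM as mean ± SD over n = 3 libraries per group unless stated.

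The transcript of Nr1d1, which encodes the REV-ERBα of the series title, was higher in every library labelled KO than in every library labelled WT, opposite to a loss of the transcript. Foxp3, which encodes the transcription factor that defines Tregs, lay at 200.6 ± 32.1 TPM in the libraries labelled KO and at 568.4 ± 107.8 TPM in those labelled WT. The list of Treg suppressive genes, among them Il10, Gzmb and Havcr2, fell against the other genes, while oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis and fatty acid genes rose. With an estimated correlation between genes, where camera also has few residual degrees of freedom, none of these 5 lists passed (smallest adjusted p = 0.5295). Epithelial markers such as Krt8 and Tff3, which the sorted cells should lack, rose together with these, by a median of 0.89 on the log2 scale, but not with an estimated correlation (adjusted p = 0.3499). No single gene passed the threshold over all 13211 genes tested.

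Nr1d1 (NM_145434, mm10 chromosome 11, 98767932 to 98775377, minus strand) was measured at 169.2, 154.3 and 141.4 TPM in the libraries labelled KO 1, 2 and 3, and at 66.3, 104.0 and 88.2 TPM in those labelled WT 1, 2 and 3. The difference was 0.86 on the log2 scale (SE 0.166, limma adjusted p = 0.1295), or 1.80-fold. The exact permutation p was 0.1, the smallest that 3 against 3 can give. The deleted exons are not given in the sources used here, and the sample labels do not say whether Nr1d1, Nr1d2 or both were removed. The value covers the whole transcript, so it does not settle whether the labels hold. Nr1d1 also overlaps Thra on the opposite strand. All directions below therefore follow the labels as given. Nr1d2, which encodes the related receptor REV-ERBβ, stood at 68.8 ± 18.2 against 61.0 ± 10.04 TPM. Its difference of 0.15 turned to -0.04 without the library labelled KO 1. Arntl (Bmal1), a clock gene that REV-ERB represses, stood at 33.2 ± 3.14 against 38.1 ± 1.74 TPM (-0.20 on the log2 scale, limma adjusted p = 0.4389).

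Among the 19 genes of the core clock and its output, 3 rose and 1 fell when p was adjusted over the list alone, and none passed over all genes. Nr1d1, Npas2 (0.84), a partner of Bmal1, and Dbp (0.57), a clock output factor, were those that rose. The list as a whole had a median of 0.06, with 10 members above 0 and 9 below, and did not pass camera (adjusted p = 0.7589). It passed with the epithelial score as a covariate (adjusted p = 0.03325), at a median of 0.00.

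**Figure D1:**
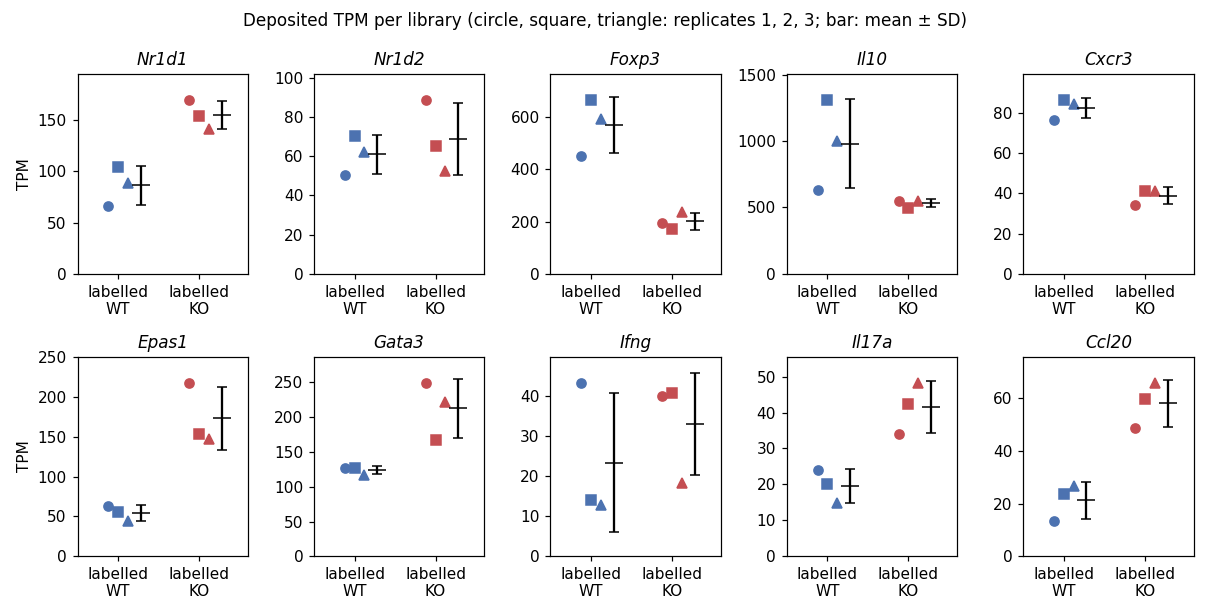
Deposited TPM (vertical axes, linear from 0) of 10 named genes in the 3 libraries labelled WT (blue) and the 3 labelled KO (red), with circles, squares and triangles for replicates 1, 2 and 3 and bars for mean ± SD. Nr1d1 lies between 141.4 and 169.2 TPM in the libraries labelled KO and between 66.3 and 104.0 TPM in those labelled WT, while Foxp3 lies lower in all 3 libraries labelled KO.

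Foxp3 (NM_054039, mm10 chromosome X, 7579676 to 7595243, plus strand) differed by -1.49 on the log2 scale (SE 0.172, limma adjusted p = 0.0678). It was measured at 195.3, 171.4 and 235.0 TPM in the libraries labelled KO and 451.4, 663.7 and 590.3 TPM in those labelled WT. Its row overlaps Ccdc22 on the opposite strand and Ppp1r3fos on the same strand. Of the 21 Treg identity genes, 4 fell and 0 rose with p adjusted over the list alone. They were Foxp3, the costimulator Icos (564.9 ± 23.6 against 890.7 ± 131.8 TPM), the TNF receptor Tnfrsf1b (-0.41) and the integrin Itgae (-0.57). Il2ra, the IL-2 receptor chain that marks Tregs, was nearly level at 300.7 ± 62.1 against 319.3 ± 42.1 TPM. Its difference of -0.10 turned positive without the library labelled KO 1 and with the epithelial covariate. The identity list had a median of -0.28 and passed camera (adjusted p = 0.03365), but not with an estimated correlation (adjusted p = 0.6385). It also missed the threshold without the library labelled KO 2 (adjusted p = 0.163) or WT 2 (adjusted p = 0.06327). The same held with the higher filter (adjusted p = 0.06686) and without the variance trend (adjusted p = 0.05884). With the epithelial score as a covariate its median was -0.03 (adjusted p = 0.8064).

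Of the 17 Treg suppressive genes tested, 9 fell and 3 rose with p adjusted over the list alone. Those that fell were Il10, an inhibitory cytokine (534.0 ± 29.7 against 980.4 ± 337.4 TPM), Gzmb, a cytolytic protease (726.6 ± 176.3 against 1264 ± 251.2 TPM), and the inhibitory receptors Havcr2 (104.2 ± 11.2 against 188.7 ± 48.3 TPM), Lag3 (-0.90) and Ctla4 (2091 ± 223.1 against 2743 ± 126.3 TPM). So did the ectoenzymes Entpd1 (-0.47) and Nt5e (-0.57), the integrin Itgb8 (-0.56) and the transcription factor Prdm1 (-0.60). The inhibitory receptor Pdcd1 (0.74), the repair factor Areg (0.45) and the cytokine subunit Ebi3 (0.42) rose. The difference of Il10, -0.815 on the log2 scale, ran from -1.10 to -0.26 over 22 other settings. The list had a median of -0.40 (camera adjusted p = 0.003668), and adjusted p = 0.5943 with an estimated correlation. Its median was -0.26 with the epithelial score as a covariate, where it no longer passed (adjusted p = 0.07094).

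The colon tissue Treg list of 23 genes held 5 that fell and 2 that rose with p adjusted over the list alone. It did not pass camera (median -0.07, adjusted p = 0.2487), except without the library labelled KO 1 (adjusted p = 0.03466). The chemokine receptors Ccr2 (243.4 ± 9.77 against 548.3 ± 135.6 TPM) and Ccr9 (-1.02) fell, as did the transcription factor Maf (-0.80). Gata3, the regulator of type 2 responses and of a subset of tissue Tregs, rose from 123.5 ± 5.92 TPM in the libraries labelled WT to 212.3 ± 42.1 TPM in those labelled KO. Pparg, a lipid-sensing receptor, rose from 10.8 ± 1.87 to 17.8 ± 1.07 TPM.

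Genes of the T helper programs moved in both directions. In the Th17 list of 17 genes, the cytokines Il17a (41.6 ± 7.14 against 19.7 ± 4.70 TPM) and Il17f (1.34) and the chemokine Ccl20 (58.0 ± 8.74 against 21.3 ± 7.10 TPM) rose in the libraries labelled KO with p adjusted over the list alone. Maf and the receptors Ccr6 (-0.67) and Il1r1 (-0.60) fell in the same test. Its median was -0.08, its mean 0.03 and the direction of its test downward, so the signs differed. It did not pass camera (adjusted p = 0.4674). In the Th2 list of 13 tested genes, Gata3, the receptor Il1rl1 (279.6 ± 129.3 against 152.1 ± 21.7 TPM) and the cytokines Il4 (2.10) and Il5 (51.2 ± 8.51 against 25.6 ± 7.26 TPM) rose with p adjusted over the list alone. The rise of Il1rl1 (adjusted p = 0.04992 over the list) hung on the library labelled KO 1, at 428.3 TPM against 216.2 and 194.2 TPM in KO 2 and KO 3. Without it the difference went from 0.79 to 0.44. Il10 and Ccr3 (9.14 ± 2.95 against 19.6 ± 2.45 TPM) fell. The Th2 median was 0.74 (adjusted p = 0.1497). The list passed without the libraries labelled KO 2 (adjusted p = 0.02309) and WT 3 (adjusted p = 0.04707) and with the epithelial covariate (adjusted p = 0.001401). In the Th1 list of 16 tested genes, 3 fell and 0 rose, among them the receptor Cxcr3 and the transcription factor Tbx21 (-0.60). Its median was -0.11 (adjusted p = 0.2). The Th1 list passed without the library labelled KO 1 (adjusted p = 0.03195), KO 2 (adjusted p = 0.0332) or WT 3 (adjusted p = 0.04535) and with the epithelial covariate (adjusted p = 0.002417). Ifng, the cytokine of that program, stood at 33.1 ± 12.8 against 23.5 ± 17.3 TPM. Its difference of 0.62 turned to -0.17 with the covariate.

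Metabolic lists rose in the libraries labelled KO against the other genes, by small amounts spread over most members and with 0 members past the threshold over their list alone. In the same libraries the epithelial markers rose, the nuclear transcripts Malat1 (-0.93) and Neat1 (-0.98) of the RNA quality list fell, and ribosomal protein genes rose by a median of 0.16. None of these 3 marker lists passed with an estimated correlation (smallest adjusted p = 0.3047). In the oxidative phosphorylation list 26 of 27 genes were above 0, with a median of 0.28 (camera adjusted p = 1.293e-08, and adjusted p = 0.5943 with an estimated correlation). Uqcrc1 of complex III stood at 163.0 ± 8.21 against 121.2 ± 11.9 TPM, and Atp5a1 of ATP synthase at 510.5 ± 23.0 against 375.5 ± 41.0 TPM. The median of this list was 0.10 with the epithelial score as a covariate (adjusted p = 0.04653) and 0.18 with the trends on length and GC content removed. In the glycolysis and hypoxia list 18 of 22 genes were above 0 (median 0.24, adjusted p = 0.0002693, and adjusted p = 0.5943 with an estimated correlation). Egln3, a hypoxia-induced hydroxylase, stood at 173.1 ± 35.8 against 108.5 ± 7.81 TPM and Aldoa at 1497 ± 141.5 against 1085 ± 83.4 TPM. The glycolysis median was 0.152 without the library labelled KO 3 (adjusted p = 0.03264) and 0.156 with the epithelial covariate. The cholesterol synthesis list had a median of 0.24 (adjusted p = 0.006915, and adjusted p = 0.5295 with an estimated correlation), which went to 0.075 with that covariate (adjusted p = 0.03325). Fatty acid uptake and oxidation had a median of 0.22 (adjusted p = 0.004027, and adjusted p = 0.5943 with an estimated correlation). Its members of smallest p were Pparg and Acaa2 (41.2 ± 4.28 against 31.3 ± 1.37 TPM). With the epithelial covariate its median was -0.04 and it did not pass (adjusted p = 0.4351). Tested alone with fry, 1 pathway list passed, cholesterol synthesis (adjusted p = 0.02249). The suppressive list did not (adjusted p = 0.129), nor did the identity, oxidative phosphorylation, glycolysis and fatty acid lists (adjusted p = 0.2499 each). Without regard to direction, 13 of the 20 pathway lists passed fry.

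**Figure D2:**
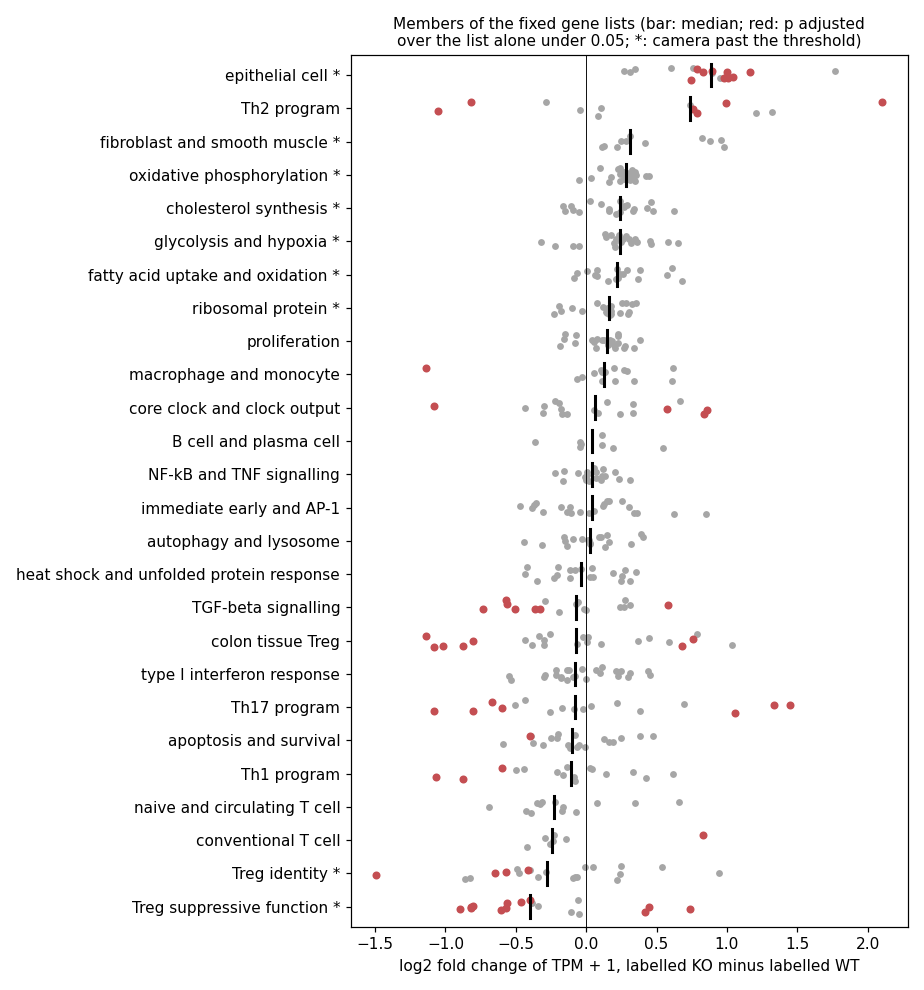
Log2 fold change of TPM + 1, labelled KO minus labelled WT (horizontal axis), of each tested member of the 20 pathway lists and 6 marker lists (rows, ordered by their median, black bar). Red points passed with p adjusted over the list alone and stars mark lists past camera, with the epithelial list at a median of 0.89 and the Treg suppressive list at -0.40.

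The other pathway lists did not pass camera. TGF-β signalling (median -0.07, adjusted p = 0.2259) held 6 genes that fell and 1 that rose with p adjusted over the list alone. Among them were the receptor Tgfbr1 (20.2 ± 1.29 against 34.7 ± 7.32 TPM), which fell, and the convertase Furin (349.7 ± 21.8 against 232.8 ± 8.03 TPM), which rose. Without the library labelled KO 1 the TGF-β list passed (adjusted p = 0.03466). Apoptosis and survival (median -0.10, adjusted p = 0.3057) held 1 gene that fell, the proapoptotic Pmaip1 (89.6 ± 3.84 against 118.8 ± 5.84 TPM). Bbc3 stood at 10.5 ± 1.04 against 16.6 ± 4.30 TPM. Type I interferon response (median -0.08, adjusted p = 0.6976) included Stat2 at 31.1 ± 3.19 against 45.3 ± 4.37 TPM and Mx1 at 6.78 ± 1.38 against 11.04 ± 5.46 TPM. It passed downward with the epithelial covariate (adjusted p = 5.575e-05). Immediate early and AP-1 genes (median 0.04, adjusted p = 0.8037) included Ier3 at 51.5 ± 11.7 against 27.98 ± 5.39 TPM and Jun at 446.9 ± 74.9 against 572.4 ± 39.9 TPM. The list passed upward without the library labelled KO 3 (adjusted p = 0.02337). Naive and circulating T cell genes (median -0.23, adjusted p = 0.2487) included Il7r at 183.4 ± 29.3 against 246.8 ± 38.1 TPM and Igfbp4 at 60.0 ± 9.57 against 38.9 ± 14.3 TPM. They passed downward without the library labelled KO 3 (adjusted p = 0.03264). Proliferation (median 0.15, adjusted p = 0.2487) included Tyms at 15.7 ± 2.05 against 12.3 ± 2.49 TPM and Mcm5 at 74.0 ± 24.2 against 55.7 ± 12.5 TPM. The list passed upward without the library labelled KO 1 (adjusted p = 0.003304) or KO 2 (adjusted p = 0.02882). NF-κB and TNF signalling (median 0.04, adjusted p = 0.4674) included Nfkbib at 149.5 ± 7.13 against 120.8 ± 12.3 TPM and Nfkbid at 138.0 ± 19.3 against 160.5 ± 17.7 TPM. Heat shock and unfolded protein response (median -0.04, adjusted p = 0.8037) included Hsph1 at 344.1 ± 47.1 against 459.6 ± 50.5 TPM and Hspa1b at 872.2 ± 164.6 against 1169 ± 100.5 TPM. Autophagy and lysosome had a median of 0.03 and a test directed downward (adjusted p = 0.9732). Ulk1 stood at 40.1 ± 2.04 against 55.2 ± 7.56 TPM and Atg16l1 at 20.7 ± 0.689 against 26.0 ± 0.836 TPM.

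Some marker lists of cells other than Tregs moved with the labels in camera at the preset correlation, and none passed with an estimated correlation. All 17 epithelial markers were above 0 in the libraries labelled KO, and 9 of them rose with p adjusted over the list alone (median 0.89, camera adjusted p = 4.242e-07, and adjusted p = 0.3499 with an estimated correlation). The keratins Krt8 and Krt18 (113.4 ± 35.2 against 54.6 ± 18.5 TPM) and the goblet cell peptide Tff3 (131.9 ± 51.8 against 55.9 ± 12.2 TPM) were among them. Krt8 averaged 717.5 TPM in the libraries labelled KO and 344.6 TPM in those labelled WT, so epithelial RNA was present in both groups. The mean log2 level of the epithelial markers was 6.64, 7.52 and 6.94 in the libraries labelled KO 1, 2 and 3. It was 6.60, 5.71 and 6.25 in those labelled WT 1, 2 and 3. Fibroblast and smooth muscle markers rose by a median of 0.31 (adjusted p = 0.02728, and adjusted p = 0.6727 with an estimated correlation). Acta2 stood at 14.5 ± 8.31 against 6.81 ± 3.41 TPM and Tagln at 15.2 ± 8.09 against 7.74 ± 4.22 TPM. Without the library labelled WT 1 their median was 0.14 (adjusted p = 0.4696). They also missed the threshold without the library labelled KO 1 (adjusted p = 0.1253) or KO 2 (adjusted p = 0.1098). The same held with voom on the recovered reads (adjusted p = 0.05905), with the higher filter (adjusted p = 0.09647) and with array weights (adjusted p = 0.06185). Neutrophil markers, with 4 tested at low levels, rose by a median of 1.73 (adjusted p = 0.009086, and adjusted p = 0.3499 with an estimated correlation). S100a8 had 4, 20 and 35 reads in the libraries labelled KO and 0 in each labelled WT, at least 14.4-fold higher against a limit of 3 reads over the group. With S100a8 at that bound the median of the list was still 1.73. Retnlg, another neutrophil gene, stood at 4.22 ± 3.45 against 0.973 ± 1.02 TPM. The neutrophil list missed the threshold without the library labelled KO 3 (adjusted p = 0.05779), with the higher filter (adjusted p = 0.2489), with array weights (adjusted p = 0.06185) and with the epithelial covariate (adjusted p = 0.1553).

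Haemoglobin transcripts, the markers of red blood cells, fell. Hbb-b1 and Hbb-bs overlap, are nearly identical and carried the same 21, 104 and 50 reads in the libraries labelled WT 1, 2 and 3. Both had 0 reads in all 3 libraries labelled KO, at least 73.3-fold lower against a limit of 3 reads over the group. Their list, in effect a single measurement, passed camera (adjusted p = 0.000218, and adjusted p = 0.3251 with an estimated correlation). Its median of -3.54 became -6.20 with both rows at their bound. The nuclear transcripts Malat1 (288.0 ± 38.9 against 546.3 ± 43.3 TPM) and Neat1 (172.8 ± 23.0 against 344.0 ± 67.3 TPM), the 2 tested members of the RNA quality list, fell (adjusted p = 0.000582, and adjusted p = 0.3047 with an estimated correlation). Ribosomal protein genes rose by a median of 0.16 (adjusted p = 0.006385, and adjusted p = 0.6727 with an estimated correlation). Rplp0 stood at 1874 ± 106.7 against 1465 ± 129.9 TPM and Rps18 at 1024 ± 103.7 against 826.0 ± 54.3 TPM. That list missed the threshold without the library labelled KO 1 (adjusted p = 0.07107) or WT 3 (adjusted p = 0.1204) and with the trends on length and GC content removed (adjusted p = 0.5929).

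The remaining marker lists did not pass camera. General T cell genes (median -0.24, adjusted p = 0.05479) included Cd3g at 362.6 ± 22.2 against 445.8 ± 34.2 TPM. In that list 1 gene rose, Cd40lg, a ligand on activated T cells, at 45.9 ± 0.989 against 26.2 ± 8.60 TPM. The list passed downward without the library labelled KO 1 (adjusted p = 0.02903), without the filter (adjusted p = 0.02879) and with quantile normalization (adjusted p = 0.04217). It also passed with immunoglobulin, haemoglobin and mitochondrial genes left out and the rest rescaled (adjusted p = 0.0459). The same held with the length and GC trends removed (adjusted p = 0.03761). Among CD8 T cell markers (median 0.77, adjusted p = 0.2106), Gzma rose from 15.5 ± 7.35 to 38.4 ± 11.7 TPM and Cd160 stood at 3.27 ± 0.249 against 2.41 ± 0.730 TPM. Gamma delta T cell markers (median -0.14, adjusted p = 0.98) included Sox13 at 4.80 ± 1.45 against 3.36 ± 0.452 TPM and Blk at 3.63 ± 0.613 against 4.51 ± 0.716 TPM. Among NK cell and innate lymphoid markers (median 0.00, mean 0.03, test directed downward, adjusted p = 0.9265), Nkg7 fell from 59.0 ± 7.21 to 37.1 ± 9.90 TPM. B cell and plasma cell markers (median 0.04, adjusted p = 0.8908) included Sdc1 at 48.4 ± 22.5 against 30.9 ± 8.77 TPM and Pax5 at 0.866 ± 0.532 against 1.37 ± 0.533 TPM. Among macrophage and monocyte markers (median 0.13, adjusted p = 0.5843) Ccr2 fell and Cd14 stood at 70.7 ± 40.3 against 43.4 ± 15.4 TPM. The list passed upward without the library labelled WT 3 (adjusted p = 0.04941) and downward with the epithelial covariate (median -0.228, adjusted p = 0.04712). Dendritic cell markers (median 0.04, adjusted p = 0.8315) included Zbtb46 at 26.6 ± 3.80 against 19.95 ± 5.05 TPM and Xcr1 at 1.96 ± 1.66 against 0.783 ± 0.383 TPM. They passed upward without the library labelled KO 3 (adjusted p = 0.04813). Among mast cell and eosinophil markers (median 0.04, test directed downward, adjusted p = 0.8908) Ccr3 fell and Hdc stood at 16.7 ± 8.88 against 6.63 ± 2.90 TPM. Endothelial markers (median 0.40, adjusted p = 0.0996) included Pecam1 at 47.6 ± 3.24 against 40.2 ± 3.48 TPM and Cdh5 at 3.72 ± 3.01 against 1.58 ± 1.47 TPM. They passed upward without the library labelled WT 1 (adjusted p = 0.02079) and without the filter (adjusted p = 0.02447). So they did with immunoglobulin, haemoglobin and mitochondrial genes left out and the rest rescaled (adjusted p = 0.02461). With the epithelial covariate they passed downward (median -0.741, adjusted p = 0.002333). Of the sex-linked genes (median -0.21, adjusted p = 0.09539), the Y-linked Ddx3y stood at 68.6 ± 7.40 against 86.2 ± 8.38 TPM and Kdm5d at 12.6 ± 0.821 against 14.9 ± 0.995 TPM. Ddx3y lay between 61.2 TPM (KO 3) and 92.9 TPM (WT 1) over the libraries, so Y-linked RNA was present in both groups. Xist did not pass the filter and was not tested. With fry the sex-linked list passed (adjusted p = 0.009063), as did the RNA quality list (adjusted p = 0.009063) and red blood cells (adjusted p = 0.015). The epithelial (adjusted p = 0.2142), neutrophil (adjusted p = 0.2221), ribosomal (adjusted p = 0.3079) and fibroblast lists (adjusted p = 0.5438) did not, and without regard to direction 0 marker lists passed.

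Over all genes tested, limma called 0 genes higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.0678. At an unadjusted p under 0.05 there were 1030 genes higher and 1038 lower, 2068 together where 661 are expected by chance. The groups did not overlap for 2774 genes, or 21% against the 10% that chance gives. At an adjusted p under 0.1, 4 genes were higher and 11 lower in the libraries labelled KO. That count hung on single libraries, at 293 and 392 without KO 3, 44 and 102 without WT 1, 2 and 0 without WT 2, and 0 and 0 without KO 1, KO 2 or WT 3. With array weights, which weight libraries by their fit, 225 genes were called higher and 357 lower. Without the library labelled WT 1 the counts were 2 higher and 12 lower.

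The 10 genes of smallest p in each direction are given as values. Epas1, which encodes HIF-2α (NM_010137, mm10 chromosome 17, 86753864 to 86833410), stood at 172.7 ± 38.9 against 54.4 ± 9.65 TPM. Its log2 fold change was 1.64 (SE 0.186, limma adjusted p = 0.0678). Higher in all 3 libraries labelled KO were also the chemokine Ccl24 (15.5 ± 6.79 against 0.648 ± 0.565 TPM, with 568 against 19 reads), and the homeobox gene Vax2 (8.28 ± 0.254 against 1.68 ± 0.565 TPM). Transglutaminase Tgm2 stood at 114.3 ± 12.8 against 56.9 ± 8.41 TPM, the noncoding 1700061F12Rik at 16.0 ± 6.53 against 2.60 ± 1.06 TPM. Ppp2r3a, a regulatory subunit of a phosphatase, stood at 7.98 ± 2.43 against 2.06 ± 0.147 TPM. Furin, given above, Tarm1 (2.94 ± 0.414 against 0.383 ± 0.142 TPM), Clca4b (5.92 ± 1.34 against 0.844 ± 0.725 TPM) and Trappc2l (48.5 ± 1.14 against 29.5 ± 3.57 TPM) complete the higher genes. Cxcr3, a chemokine receptor of effector T cells (NM_009910, mm10 chromosome X, 101731535 to 101734147), stood at 38.8 ± 4.02 against 82.2 ± 5.07 TPM. Its log2 fold change was -1.07 (SE 0.114, limma adjusted p = 0.0678). Lower in all 3 libraries labelled KO were also Foxp3, Leng8 (71.4 ± 3.86 against 125.5 ± 6.63 TPM), the tyrosine kinase Matk (20.02 ± 3.06 against 51.8 ± 9.71 TPM), Malat1, Hbb-b1 and Hbb-bs. The rows of the microRNAs Mir709 and Mir10a had 0 reads in the libraries labelled KO against 15 and 9 reads in those labelled WT, at least 6.34-fold and 3.98-fold lower, and Mir7-1 had 62 against 111 reads. Mir709 lies inside Rfx1 and Mir7-1 inside Hnrnpk on the same strand, so their reads cannot be told from those of their hosts.

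The libraries did not separate by genotype alone. On the first principal component, with 39.6% of the variance, the libraries labelled KO 1 and KO 2 lay at -27.2 and -36.8. Those labelled WT 2 and WT 3 lay at 39.9 and 17.5, while KO 3 and WT 1 lay at 3.3 and 3.2. KO 3 and WT 1 were apart on the second component, at -35.7 and -8.8, and on the third, at -11.7 and 33.4. The correlation across genes was 0.9661 between KO 3 and WT 1, above the 0.9567 and 0.9572 of KO 3 with the others labelled KO, genes not being independent replicates. For WT 1 it was nearly as high with WT 3 of its own group, at 0.9647, and 0.96 with WT 2. Foxp3, at 235.0 TPM in KO 3 and 451.4 TPM in WT 1, and Nr1d1, at 141.4 and 66.3 TPM, were on the side of their labels in these libraries.

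**Figure D3:**
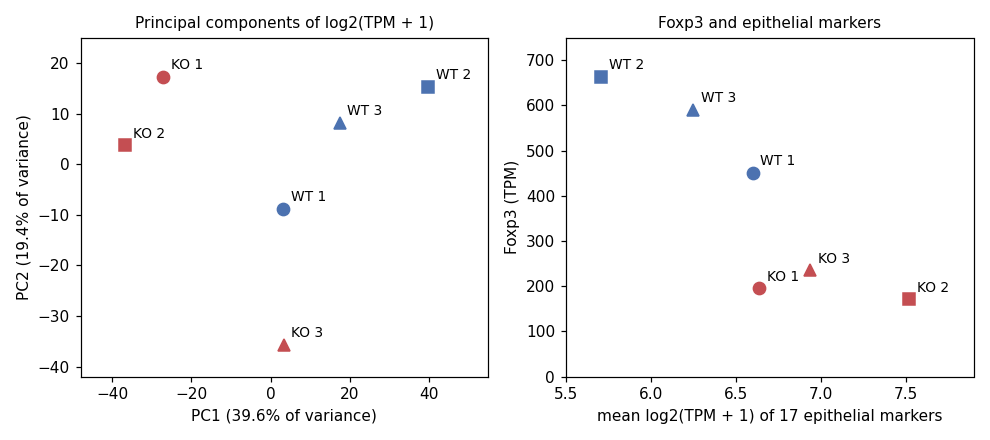
Left, positions of the 6 libraries on the principal components of log2(TPM + 1), with 39.6% and 19.4% of the variance on the axes; right, Foxp3 (TPM, vertical axis from 0) against the mean log2(TPM + 1) of the 17 epithelial markers, with libraries labelled WT in blue and KO in red. The libraries labelled KO 3 and WT 1 lie at 3.3 and 3.2 on the first component, and KO 1 and WT 1, with nearly equal epithelial means of 6.64 and 6.60, hold 195.3 and 451.4 TPM of Foxp3.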

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

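Of the alternatives, voom on recovered or thinned reads, the epithelial covariate, the removal of length and GC trends and the limit on short transcripts were chosen after seeing the data. Nr1d1 stayed higher in the libraries labelled KO and Foxp3 lower under all 22 other settings, at 0.69 to 1.20 and -1.65 to -1.12 on the log2 scale. Among the named genes the sign turned for Nr1d2, Il2ra, Ifng, Cd14 and Cdh5, none of which had an unadjusted p under 0.05 in the chosen fit. Of the 12 lists past camera, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis and RNA quality passed under all 22 settings, and red blood cells under the 21 in which they were measured.

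With array weights 225 genes were called higher and 357 lower in the libraries labelled KO, and Nr1d1 passed at 0.844 (limma adjusted p = 0.03033), against 0.03033 to 0.8919 over its alternatives. The weights ranged from 0.43 for the library labelled KO 3 to 2.10 for the one labelled WT 3. The next lowest was 0.59 for WT 1, so the weights discounted the libraries that lay between the others on the first principal component. With reads thinned to the smallest library 1 gene was called higher and 1 lower, without transcripts under 300 bases 3 and 6, and at an adjusted p under 0.1 4 and 11. For the thinned reads, the short transcripts and the weights the cause was not tested. Leaving out each library in turn gave 0 to 2 genes higher, 0 to 12 lower and 5 to 10 pathway lists past camera. The 2 and 12 were found without the library labelled WT 1, and the 10 without the one labelled KO 1. The genes at an unadjusted p under 0.05 went from 2068 to 1188 without KO 2, to 1095 without WT 2 and to 3720 with array weights.

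With the epithelial score as a covariate, which correlates with the labels and leaves fewer degrees of freedom, 486 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.8919. The macrophage list then passed downward at -0.228 (adjusted p = 0.04712) and the endothelial list at -0.741 (adjusted p = 0.002333), and the cause was not tested. The median of the oxidative phosphorylation list went from 0.283 to 0.101 (adjusted p = 0.04653) with that covariate, and to 0.177 (adjusted p = 2.286e-05) with length and GC trends removed. Replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.00, -0.22 and -0.04). With the replicate block 0 genes were called higher and 0 lower, 1819 genes had an unadjusted p under 0.05, and 7 pathway lists passed, the Th2 program among them (adjusted p = 0.04008). Summing rows of a symbol was not run, because each symbol has a single row. Scaling moved the median of all genes by little, from -0.00281 to 0.0105 with median-of-ratios factors. Depth limits genes such as Mir709 and Mir10a, whose 15 and 9 reads in the libraries labelled WT bound any difference.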

Other observations

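The tests below were chosen after the results were seen, except the counts of splits other than that with array weights, and the test of the share of epithelial RNA in the split that exchanges KO 3 and WT 1, where the count of shared genes and its use for the verdict came afterwards. The patterns weighed last were also chosen that way: the oxidative phosphorylation list was weighed first, and after its 2 tests had been run it was replaced by the structure of the libraries labelled KO 3 and WT 1. Those 2 tests left the share of epithelial RNA open for that list (median 0.10 with the covariate). They argued against transcript length and GC content as the whole cause only. The median went from 0.28 to 0.18 with those trends removed, so a part of the rise went with them. Directions follow the labels, and the higher Nr1d1 in the libraries labelled KO does not settle whether these hold.

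Guanylate-binding proteins, large GTPases that interferon induces and that act in defence inside cells, were lower in the libraries labelled KO. Families were formed after the data had been seen from the letters that open the gene symbols, and 218 were tested with camera, of which 18 passed upward and 14 downward, and none with an estimated correlation (adjusted p = 0.7982). The Gbp family had the smallest p, with 9 of 10 genes below 0 and a median of -0.73 (adjusted p = 1.07e-07, and adjusted p = 0.7982 with an estimated correlation). Gbp2b stood at 16.1 ± 5.03 against 74.6 ± 33.7 TPM, Gbp10 at 5.48 ± 0.483 against 13.04 ± 1.34 TPM, Gbp3 at 113.0 ± 9.88 against 196.7 ± 40.0 TPM and Gbp9 at 38.4 ± 4.20 against 62.3 ± 3.87 TPM. Gbp2 was the exception at 90.1 ± 7.97 against 86.2 ± 15.7 TPM. These genes are close paralogs, and how reads were assigned between them was not tested. The median of the family lay between -0.81 and -0.54 under 22 other settings, all of which start from the same assignment. It passed camera in all 10 settings in which families were tested again, at an adjusted p of at most 4.662e-06, including the epithelial covariate (adjusted p = 3.714e-07).

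Chemokine receptors of the Ccr family had a median of -0.42, with 8 of 10 genes below 0 (camera adjusted p = 0.004254, and 0.7982 as adjusted p with an estimated correlation). Ccr2, Ccr3, Ccr6 and Ccr9 lay at -0.67 or lower, whereas Ccr4 (211.6 ± 15.4 against 220.6 ± 43.7 TPM) and Ccr8 (255.5 ± 63.2 against 233.1 ± 14.6 TPM), which mark Tregs in tissue, were nearly level. With the epithelial covariate the Ccr family did not pass (adjusted p = 0.4921). The Ndufa subunits of complex I had a median of 0.31 with 13 of 13 genes above 0 (adjusted p = 6.997e-05, and adjusted p = 0.7982 with an estimated correlation), the keratins 0.83 and the claudins 0.79 (both 0.7982 as adjusted p with an estimated correlation). Of these, the claudins turned to -0.01 with the epithelial covariate, and none of the 3 passed with it (adjusted p = 0.4298, 0.3532 and 0.706). The epithelial score itself includes keratins and the claudin Cldn7, so for the keratins and claudins this outcome was largely set in advance. The 300 zinc finger genes of the Zfp family had a median of -0.18, with 230 below 0 (adjusted p = 7.576e-05, and adjusted p = 0.7982 with an estimated correlation). It lay between -0.26 and -0.01 under 22 other settings. The Zfp family passed camera in 9 of the 10 settings in which families were tested again. Among these was the removal of length and GC trends (adjusted p = 0.005947), while with the covariate it did not pass (adjusted p = 0.6818). Across genes, the median log2 fold change fell from 0.073 in the 2643 shortest to -0.094 in the 2642 longest transcripts.

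Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The counts of genes called higher and lower were 0 and 0 for the real split, which all 10 splits reached, and at most 0 and 1 for the others. For genes with an unadjusted p under 0.05 the real split gave 2068 and the highest other 2322, so 2 of the 10 splits gave as many. With array weights the real split gave 582 and the highest other 1448, again 2 of 10. For pathway lists past camera the real split gave 6 and the highest other 9, and 5 of 10 gave as many. The split that gave 2322 and 1448 is the one that exchanges the libraries labelled KO 3 and WT 1, which points to a structure of the samples.

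That structure sets KO 1 and KO 2 against WT 2 and WT 3, with KO 3 and WT 1 between them. An exchange of the labels of KO 3 and WT 1 would put KO 3 near 0 and WT 1 near 1, where 0 is WT 2 and WT 3 and 1 is KO 1 and KO 2. Labels as given would put them the other way round. Over the 574 genes called between the 4 other libraries, KO 3 had a median position of 0.50 and WT 1 of 0.47. The quartiles ran from 0.25 to 0.76 for KO 3 and from 0.31 to 0.64 for WT 1. Both medians lie in the middle, but the genes were chosen as far apart in the 4 other libraries. That choice draws libraries left out of it toward the middle, whatever their state. The test therefore does not decide between an exchange, a mixed state and the labels as given. Of the 15 genes with the smallest p between those 4 libraries, KO 3 lay on the KO side of WT 1 for 9. The share of epithelial RNA stays open too: with the epithelial score as a covariate the exchanged split had 1507 genes with an unadjusted p under 0.05, which met the bar set on the count beforehand, but only 1090 of them were among the 2322 without it, so that bar was met partly by other genes. A difference between animals or preparations stays open and was not tested.

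For the higher Nr1d1 in the libraries labelled KO, counting error is argued against as the whole cause. Its counting noise on reads thinned to the smallest library was 0.02691, against a log2 fold change of 0.86. The 1765 other genes with a mean TPM within 2-fold of it had a median log2 fold change of -0.01 (SD 0.32). Of these genes, 25 reached 0.86. The scaling to TPM had already left the median of all genes tested at -0.00281, so this median could hardly have come near 0.86. It shows no shift of that size shared by genes at its level, and otherwise does not decide on depth or scaling. An exchange of the KO and WT labels cannot be told apart from labels as given. The mean log2 level of 5 genes that REV-ERB represses (Arntl, Clock, Npas2, Cry1 and Nfil3) differed by 0.06 and overlapped between the groups. The members differed in sign, with Npas2 (0.841) and Cry1 (0.086) above 0 and Arntl (-0.195), Clock (-0.133) and Nfil3 (-0.3) below. Only Npas2 was without overlap, higher in the libraries labelled KO. Collection at another phase of the clock also stays open, since the score of 6 genes in phase with Nr1d1 minus the repressed genes differed by 0.15 with overlap. A hypothesis from outside these data is a transcript that persists after part of the gene is deleted and escapes its own repression, which was not tested here.

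For the lower Foxp3, fewer T cells among epithelial cells is argued against as the whole cause. The mean of 6 T cell genes (Cd3d, Cd3e, Cd3g, Cd4, Cd2 and Cd28) differed by -0.26, and Foxp3 relative to them by -1.23, lower in all 3 libraries labelled KO. With the trends on transcript length and GC content removed, the log2 fold change of Foxp3 was -1.52, against -1.49 before. The median log2 fold change was only -0.036 among the transcripts of 3090 to 4437 bases, which include Foxp3. Removing a length trend of that size could hardly have brought -1.49 near 0, so for length the outcome was fixed beforehand. The values show only that trends shared by genes were too small to be the whole cause. A larger share of T cells other than Tregs in the sorted cells cannot be told apart from a lower level per Treg, as the 20 other identity genes differed by -0.17 with overlap and their level in other T cells is not known from these libraries. The loss of REV-ERB itself, the biological explanation that the design names, stays open and untested apart from these. The groups also differed without overlap in depth, in Malat1 and Neat1, and in Hbb-b1, with 0 reads against 21, 104 and 50. A difference in preparation between the groups therefore goes with the labels. For Foxp3 and for Nr1d1 it stays open and was not tested.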
